A study of Mus musculus with 10 samples.

How the data were processed

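Total RNA from mouse neurons treated with DMSO (5 samples) or SP600125 (5 samples) was labelled and hybridised to Affymetrix whole-transcript arrays, 1 array per sample, per the labels' protocols. The deposited values were log2 expression values, with 1 value per probe set and array in 1 table of 35556 probe sets, and they were made with oligo 1.14.0, per the submitters' processing notes. The background correction, the normalization between arrays and the summarization of probes are not given in the sources used here. That the scale is log2 was taken from the values, with a lowest value of 1.8984 and a highest of 13.8294 over all arrays. Array medians over all probe sets were close but not equal (5.56 ± 0.04 for DMSO and 5.66 ± 0.03 for SP600125, mean ± SD, n = 5). A log2 array value compresses changes of dim probe sets towards the background, and a difference in signal over background between arrays changes bright and dim genes in opposite directions. The values were used as deposited, without further normalization, in the primary analysis.

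Samples were grouped by the treatment in their labels, and the drug batch (1 or 2) was taken from the labels as well. Gene names came from a probe table of the platform annotation, which can be old. Of the probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 were unnamed there. Only probe sets with 1 symbol were named, and each gene was represented by its probe set with the highest mean over all arrays. This gave 19938 genes, 999 of them with more than 1 probe set. The gene identifiers of 21698 probe sets matched a mouse RefSeq gene table (assembly GRCm38.p6), and 0 symbols needed an update. That table served for names and gene lengths only, and no coordinates are given because the build behind the array is not stated.

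Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values with treatment and drug batch as terms, leaving 7 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and a second count required an absolute log2 change of 1 (2-fold). All log2 changes are SP600125 minus DMSO with the moderated SE of limma. The interaction of treatment and batch tested whether the response differed between drug lots, and the batch term of the additive model gave the difference between batches. The comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined.

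The 37 gene lists, with 691 members written and 636 measured, covered JNK pathway components, the AP-1 family, immediate early and activity genes, ERK feedback, axon injury and regeneration, pro-apoptotic genes, targets of the aryl hydrocarbon receptor, NRF2, ATF4, p53, FoxO, Wnt, and TGF-beta and BMP, and ER chaperones and heat shock genes. They also covered NF-kB and inflammatory genes, interferon-stimulated genes, cholesterol synthesis, hypoxia and glycolysis, the respiratory chain, ribosomal proteins, the circadian clock, the Notch pathway and the cell cycle. Neuronal lists were presynaptic, postsynaptic, microtubule and transport, and axon guidance genes. Cell type lists were pan-neuronal, glutamatergic, GABAergic, neural progenitor, astrocyte, oligodendrocyte lineage, microglia and macrophage, pluripotency, and fibroblast and endothelial markers. Lists were tested with camera at the preset inter-gene correlation of 0.01, adjusted over the 37 lists, with an estimated correlation and fry beside it. Members were also adjusted over the list alone. After seeing the data, each list median was also set against 10000 random lists of genes within 150 ranks of each member's mean signal, and the mean of the fibroblast and endothelial markers minus that of the astrocyte markers on each array after cyclic loess was compared between the groups by an exact permutation test.

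Named genes were the 12 largest rises and the 12 largest falls among genes past the threshold whose SP600125 arrays all lay on 1 side of the DMSO arrays of the same batch in both batches, leaving out symbols of predicted or unnamed genes and of olfactory and vomeronasal receptors. From each list came the up to 4 largest changes past the threshold, or the largest change where none passed. Jun, Fos, Atf3, Egr1, Mapk8, Mapk9, Mapk10, Cyp1a1 and Cyp1b1 were always named, and so were the 5 genes with the smallest interaction p. Nr4a3, Npas4 and Klf4 and the gene families of the closing observations were chosen after their values were seen.

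The fit was tested on simulated data with the gene means and spread of the 19938 genes of the SP600125 comparison, in which 200 genes were changed. It recovered 26.9% of the genes changed by 0.25 on the log2 scale, 91.0% of those changed by 0.5 and 100% of those changed by 1, all with the right sign, with 7 calls among the unchanged genes. With 1 of 37 lists shifted, the list test called 1 list, the shifted one. Errors were drawn for each gene independently, so this run could not show false list calls that come from correlated genes. Nor could it show false gene calls that come from differences of whole arrays. The recovery holds for 200 changed genes, far fewer than the 9351 called in the data. In the data the estimated correlation within the presynaptic list was 0.835.

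Alternatives fixed beforehand were no batch term, the replicate letter as a block, quantile normalization, median centring of each array, only genes above the median level, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, all probe sets, each drug batch alone and leaving out each array in turn. Cyclic loess between arrays, median centring on named genes, leaving out DMSO replicate b with SP600125 replicate a, the median of the olfactory receptor genes as a covariate, and camera with an estimated correlation after cyclic loess were added after seeing the data. Splits of the arrays were counted on 100 of the 126 ways to divide 10 arrays into 5 and 5, and for drug batch on 100 of the 210 ways to divide them into 4 and 6. Unnamed probe sets were left out of the gene counts.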

Results

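Transcript levels were measured on Affymetrix whole-transcript arrays in mouse neurons that had reached terminal differentiation in culture. The cells received SP600125, an inhibitor of the JUN N-terminal kinases (JNK), or its solvent DMSO. SP600125 was applied at 25 µM in 3 doses spaced 2 hours apart, and DMSO was applied in the same way. Each group held 5 biological replicates, named a to e. Replicates a and b belonged to drug batch 1 and replicates c, d and e to drug batch 2, where a batch is a separate lot of SP600125. The labels do not say that each replicate was a separate culture, so p-values measure only the spread between these samples, which may be technical. Each array gave 35556 probe sets, and 19938 genes were tested. Correlations between arrays across probe sets ran from 0.990 to 0.993 within DMSO and from 0.987 to 0.992 within SP600125, and from 0.976 to 0.990 between the groups. No pair of arrays was a duplicate, since the closest pair still differed by a mean of 0.16 on the log2 scale. The number of arrays limits the precision of every value below.

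The first comparison asked which genes responded to SP600125. Nes, which encodes the intermediate filament nestin, fell by 1.34 on the log2 scale (SE 0.06, n = 5 per group), the largest fall of any gene named here. Jun, the best known target of JNK, fell by 0.56 (SE 0.06), and the transcripts of the 3 kinases themselves fell as well. All 17 measured genes of cholesterol synthesis and all 19 presynaptic genes were lower after SP600125. Fewer genes rose, and among them were Nr4a1 and Nr4a2, orphan nuclear receptors of the immediate early class, which rose by 0.78 (SE 0.09) and 0.66 (SE 0.08).

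With limma and a term for drug batch, 9351 of the 19938 genes changed at a Benjamini-Hochberg adjusted p under 0.05, of which 3389 rose and 5962 fell. Most changes were small. The median absolute log2 change of the called genes was 0.30, 115 genes rose at least 1.5-fold and 275 fell at least 1.5-fold, and 6 genes changed at least 2-fold, 4 of them upward and 2 downward. That last count was 19 without DMSO replicate b and 24 without SP600125 replicate b. The share of calls that were rises was 36.2%, and it moved with the scaling of the arrays. It was 25.0% after quantile normalization, 14.9% after centring each array on the median of all probe sets, 34.7% after cyclic loess and 46.9% after centring on named genes alone. SP600125 and DMSO arrays were fully separated, the same way, within both drug batches for 6230 genes, or 31.2% of those tested, against 1.67% by chance. Of these genes 5910 passed the threshold. Genes are not independent, and an array-wide difference between the groups would separate many of them at once. The excess over chance thus does not show responses of single genes.

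Signal level moved with the treatment. Genes with a mean log2 signal between 4 and 5 had a median change of 0.15 (1261 rose, 112 fell), and genes between 8 and 9 had a median change of −0.24 (36 rose, 1140 fell). The spread of gene values was narrower on the SP600125 arrays, with an SD of 1.68 ± 0.03 against 1.81 ± 0.03 on the DMSO arrays (mean ± SD, n = 5, exact two-sided permutation p = 0.00794). The median of 1027 olfactory receptor genes on an array was 3.89 ± 0.04 after SP600125 and 3.65 ± 0.07 after DMSO (mean ± SD, n = 5, exact two-sided permutation p = 0.00794). The median change of these genes was 0.23, against 0.11 for genes of their level, and 0.12 after cyclic loess, where 258 rose and 5 fell. The median of each list called by camera is given below beside that of random lists matched on signal level.

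**Figure D1:**
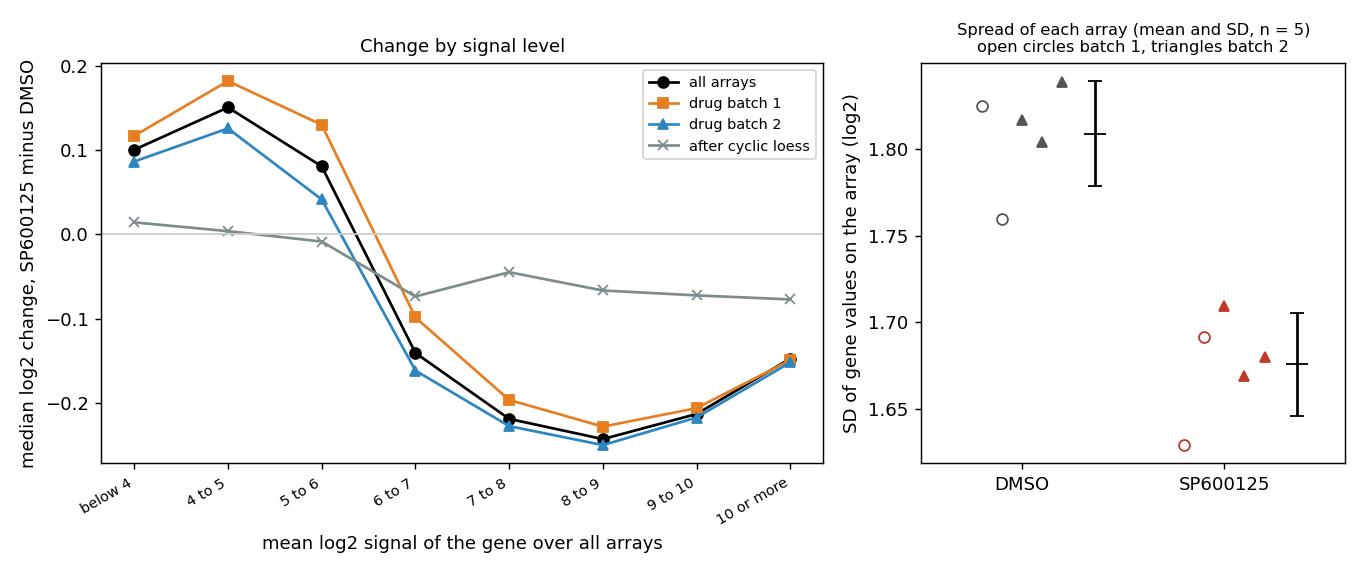
The left panel plots the median log2 change (SP600125 minus DMSO) of genes grouped by their mean log2 signal, over all arrays, in each drug batch alone and after cyclic loess. The right panel plots the SD of gene values on each array with the mean and SD of each group, and all 5 SP600125 arrays lie at or below 1.71, under the lowest DMSO array at 1.76.

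Apart from Nes, the largest falls were those of Rgs4, a regulator of G protein signalling (−1.01, SE 0.14), and Thbs1, the matrix glycoprotein thrombospondin (−0.99, SE 0.12). Rgs4 hardly differed between the b arrays, at 8.20 on SP600125 replicate b and 8.25 on DMSO replicate b. Fbln5, the elastic fibre protein fibulin (−0.94, SE 0.15), and Tmem255a (−0.91, SE 0.14) came next, then Mblac2 (−0.90, SE 0.12). Cacna2d1, an auxiliary subunit of voltage-gated calcium channels (−0.90, SE 0.11), Hsd17b7, an enzyme of cholesterol synthesis (−0.90, SE 0.11), and Col12a1, a fibril-associated collagen (−0.90, SE 0.06), fell by similar amounts. So did Elovl6, a fatty acid elongase (−0.89, SE 0.09), Rem2, a small GTPase (−0.89, SE 0.11), and Pnmal2 (−0.89, SE 0.09). Adjusted p-values of these 12 genes from limma ran up to 0.000478, and the one of Nes was 1.23e-08.

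The largest rise was that of Aqp8, a water channel (1.23, SE 0.11, or 2.35-fold, limma adjusted p = 1.83e-05). Rdh18-ps, a pseudogene of the retinol dehydrogenases (1.11, SE 0.16), Sp140, a nuclear body protein (1.04, SE 0.12), and AI506816 (1.01, SE 0.09) also rose more than 2-fold. AI506816 stayed under 2-fold after quantile normalization (0.90), median centring of each array (0.91) and cyclic loess (0.89), but not after centring on named genes (1.04). Srsy rose by 1.00 (SE 0.09) but is uncertain, since 19 probe sets of the array carry that name and its copies cannot be told apart. Ifnz, interferon zeta, rose by 0.86 (SE 0.10), Zfp600, a zinc finger gene, by 0.83 (SE 0.15), Igha, an immunoglobulin heavy chain, by 0.77 (SE 0.08), and Svs3a, a seminal vesicle secretory gene, by 0.77 (SE 0.08). Dppa5a, known from pluripotent cells, rose by 0.72 (SE 0.09), and Socs2, a suppressor of cytokine signalling, by 0.72 (SE 0.06). With Nr4a1 these are the 12 largest rises, and several are dim on the arrays: Zfp600 had a mean log2 level of 2.81 and Rdh18-ps of 3.94 after DMSO. The Zfp600 level lay under the median of olfactory receptor genes after DMSO (3.65), so the size of its rise is uncertain.

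**Figure D2:**
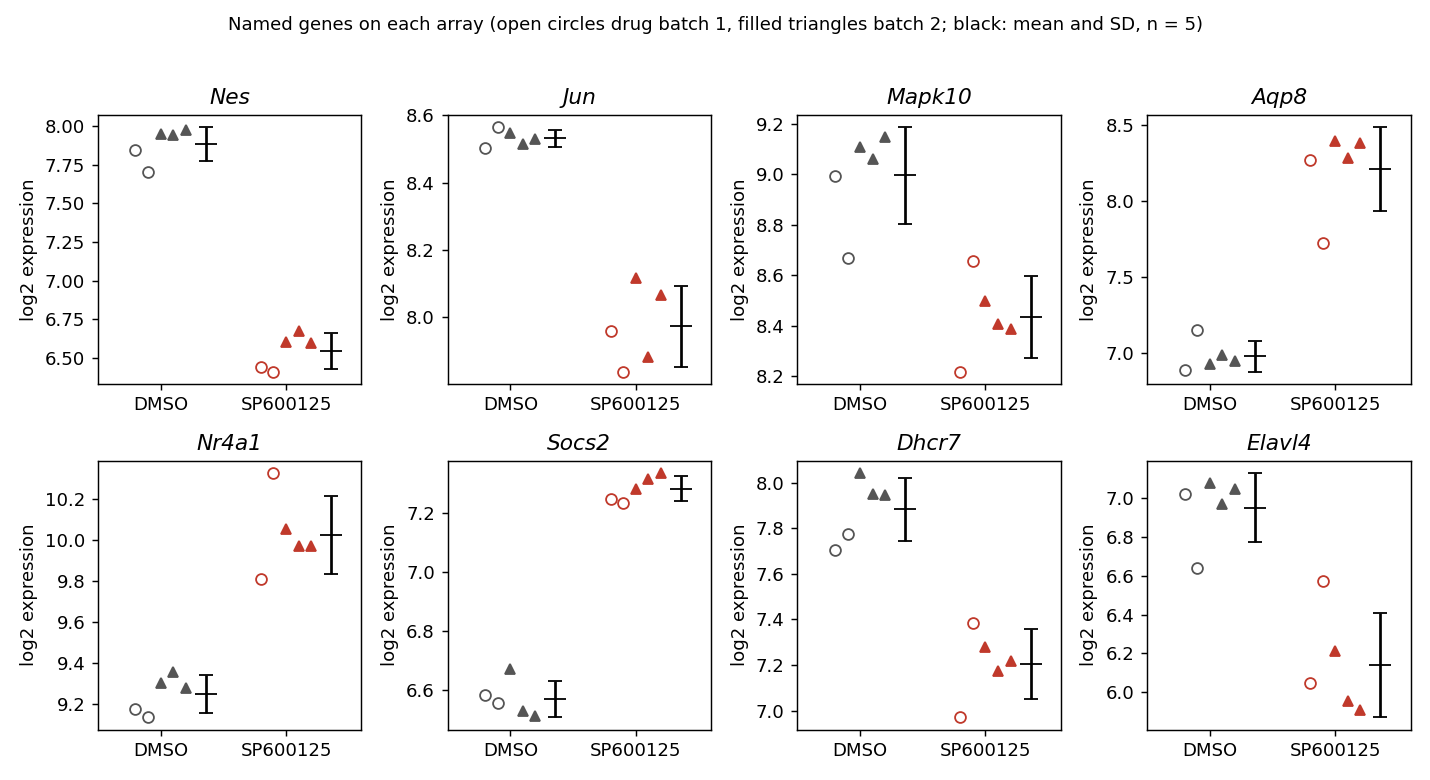
Each panel plots the log2 expression of 1 gene on each of the 10 arrays by treatment, with the mean and SD of each group (n = 5) in black. Open circles are drug batch 1 and filled triangles drug batch 2, and each axis covers only the range of its gene. Nes lay between 7.71 and 7.97 on the DMSO arrays and between 6.41 and 6.68 on the SP600125 arrays.

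Of 20 measured components of the JNK pathway, 17 fell, none rose and 3 did not pass (18 fell when adjusted over the list alone). The neuronal kinase Mapk10 (JNK3) fell by 0.56 (SE 0.09), Mapk9 (JNK2) by 0.45 (SE 0.09) and Mapk8 (JNK1) by 0.34 (SE 0.08). Dusp8, a phosphatase that acts on JNK, fell by 0.69 (SE 0.10), the upstream kinase Map3k4 by 0.51 (SE 0.08) and the scaffold Mapk8ip2 by 0.50 (SE 0.10). The list median was −0.34 against −0.21 for lists matched on level, of which 0.540% were as low. The list was called lower by camera (adjusted p = 4.22e-05) but not when gene correlation was estimated (adjusted p = 0.524 with an estimated correlation). After cyclic loess 8 of the 20 genes fell, and Mapk8 did not pass (−0.15, limma adjusted p = 0.0851). SP600125 replicate a minus SP600125 replicate b had a median of −0.26 over the list, against −0.11 for level-matched lists, of which 0.66% were as low. The list median was −0.25 in drug batch 1 and −0.38 in drug batch 2. Of 16 genes of the AP-1 family, the transcription factors downstream of JNK, 1 rose, 3 fell and 12 did not pass, and the list was not called (camera adjusted p = 0.877). Jund fell by 0.55 (SE 0.09) with Jun, Atf2 fell by 0.21 (SE 0.06), and Fosb rose by 0.24 (SE 0.07). Fos (0.14, SE 0.11, limma adjusted p = 0.319) and Atf3 (0.19, SE 0.08, limma adjusted p = 0.077) did not pass. After cyclic loess 2 genes of the family rose and 3 fell, Atf2 did not pass (−0.05, limma adjusted p = 0.543), and Atf3 passed at 0.35 (limma adjusted p = 0.00624). Atf3 also passed after quantile normalization at 0.30 (limma adjusted p = 0.0139) and after centring on named genes at 0.22 (limma adjusted p = 0.0414).

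Of 33 immediate early and activity genes, 6 rose, 6 fell and 21 did not pass, and the list was not called (camera adjusted p = 0.493). Besides Nr4a1 and Nr4a2, Nr4a3 (0.32, SE 0.08), Npas4 (0.29, SE 0.06), an activity-dependent transcription factor, Klf4 (0.28, SE 0.07) and Fosb rose. Nptx2, a secreted synaptic protein, fell by 0.67 (SE 0.13) and Ier2 by 0.48 (SE 0.07), while Egr1 had a change of −0.08 (SE 0.06, limma adjusted p = 0.245). The list median of −0.03 stood above that of level-matched lists (−0.16), with 0.170% of them as high, and after cyclic loess the list was called higher (camera adjusted p = 0.00304), but not with gene correlation estimated (adjusted p = 0.352 with an estimated correlation). After cyclic loess 10 of them rose and 5 fell. Over this list SP600125 replicate a minus SP600125 replicate b had a median of −0.18, and 0.75% of level-matched lists were as low. Of 15 ERK feedback genes, 3 rose and 4 fell, and after cyclic loess 7 rose and 4 fell. Their list median was 0.02 against −0.19 for level-matched lists, of which 0.13% were as high, and the list was not called (camera adjusted p = 0.957, and 0.187 after cyclic loess). Spry2, an inhibitor of receptor tyrosine kinase signalling, rose by 0.42 (SE 0.07), while Spred2, another inhibitor of the pathway, fell by 0.67 (SE 0.07), Ccnd1 (cyclin D1) by 0.66 (SE 0.07) and the phosphatase Dusp4 by 0.62 (SE 0.14). Of 19 axon injury and regeneration genes, 1 rose and 10 fell, with a fall of 0.56 (SE 0.15) for the neuropeptide Npy and of 0.51 (SE 0.12) for the peptidase Ecel1, and the list was not called (camera adjusted p = 0.0891). DMSO replicate b minus DMSO replicate a had a median of −0.12 over this list, with 1.76% of level-matched lists as low, and SP600125 replicate a minus b of −0.20, with 1.13% as low. Ecel1 was higher on SP600125 replicate b (7.73) than on DMSO replicate b (7.48), against its fall.

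Cholesterol synthesis genes were lower. All 17 measured genes fell, also when adjusted over the list alone, with changes from −0.68 to −0.27. Dhcr7, the enzyme of the last step to cholesterol, fell by 0.68 (SE 0.08), the isomerase Idi1 by 0.61 (SE 0.07), the epoxidase Sqle by 0.56 (SE 0.08) and the dehydrogenase Nsdhl by 0.56 (SE 0.11). The median was −0.50, against −0.22 for level-matched lists, none of which was as low. The list was called lower by camera (adjusted p = 2.27e-07) and after cyclic loess (adjusted p = 2.98e-07), but in neither case with gene correlation estimated (adjusted p = 0.524 and 0.323 with an estimated correlation). After cyclic loess 15 of the 17 fell. Within DMSO, replicate b lay 0.12 below replicate a at the median of these genes, and 8.22% of level-matched lists were as low. SP600125 replicate a minus SP600125 replicate b had a median of −0.31, against −0.12 for level-matched lists, of which 0.37% were as low.

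Synaptic and neuronal genes were lower after SP600125. All 19 presynaptic genes fell (19 also when adjusted over the list alone), among them Napb (−0.78, SE 0.11), Cplx1 (complexin, −0.73, SE 0.11), the vesicle protein Sv2a (−0.68, SE 0.13) and Syp (synaptophysin, −0.67, SE 0.13). Of 21 postsynaptic genes, 18 fell and 3 did not pass (20 fell when adjusted over the list alone), with Gria1, a glutamate receptor subunit, at −0.69 (SE 0.09), the scaffold Dlg4 at −0.54 (SE 0.10), the adhesion molecule Nlgn3 at −0.53 (SE 0.07) and Homer2 at −0.50 (SE 0.08). Of 31 axon guidance genes, 24 fell and 7 did not pass (25 fell when adjusted over the list alone), including the guidance cues Sema3c (−0.74, SE 0.12) and Slit2 (−0.61, SE 0.10) and the receptors Plxna4 (−0.60, SE 0.10) and Epha3 (−0.57, SE 0.08). Of 22 microtubule and transport genes, 18 fell and 4 did not pass, also when adjusted over the list alone, with Map1a at −0.64 (SE 0.11), Stmn4 at −0.58 (SE 0.07), Mapt (tau) at −0.58 (SE 0.11) and Map1b at −0.55 (SE 0.11). Of 16 pan-neuronal markers, 9 of which are also in another list, 15 fell and 1 did not pass, also when adjusted over the list alone. The RNA-binding proteins Elavl4 (−0.81, SE 0.12) and Elavl3 (−0.59, SE 0.12), the neurofilament Nefl (−0.60, SE 0.15) and Syn1 (synapsin, −0.58, SE 0.12) were examples.

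The medians of these 5 groups were −0.46 (presynaptic), −0.41 (postsynaptic), −0.33 (axon guidance), −0.43 (microtubule) and −0.46 (pan-neuronal), against −0.18 to −0.21 for level-matched lists. The share of level-matched lists as low was 0.07% for axon guidance, and none was as low for the other 4 groups. Each was called lower by camera, with adjusted p of 5.33e-06, 5.33e-06, 5.33e-06, 5.75e-05 and 0.000105 in the same order, and none was called with gene correlation estimated (adjusted p = 0.524 with an estimated correlation for the first 4 and 0.547 for the pan-neuronal markers). After cyclic loess 13, 13, 13, 14 and 11 of their genes fell, while 1 axon guidance gene and 1 microtubule gene rose. The same genes also differed between arrays of 1 group. DMSO replicate b lay below DMSO replicate a, at the median by 0.29, 0.22, 0.21, 0.27 and 0.31, and SP600125 replicate a lay below SP600125 replicate b, at the median by 0.52, 0.34, 0.30, 0.36 and 0.59. The list medians in drug batch 1 alone were −0.23, −0.31, −0.21, −0.26 and −0.22, and in drug batch 2 alone −0.60, −0.47, −0.43, −0.54 and −0.61. On a scale from 0 (batch 2 DMSO mean) to 1 (batch 2 SP600125 mean), DMSO replicate b lay at 0.529 over these genes. SP600125 replicate b lay at 0.435, so the b arrays showed no fall along this scale. The a arrays lay at 0.0652 (DMSO) and 1.18 (SP600125), so the batch 1 medians rest on them.

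**Figure D3:**
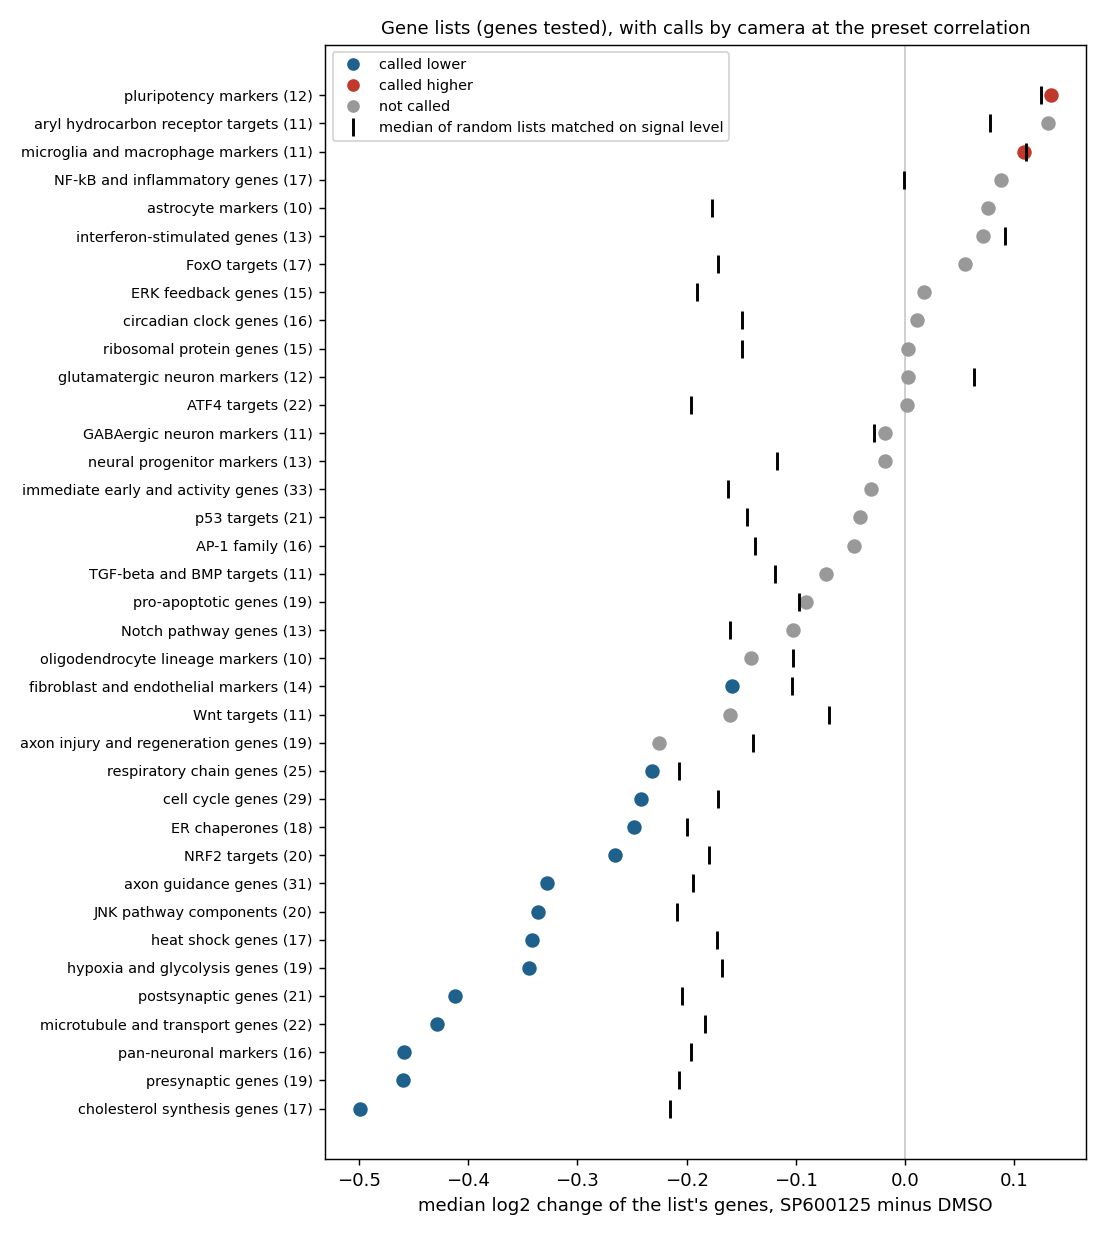
Each point is the median log2 change (SP600125 minus DMSO) of the genes of 1 list, with the number of genes tested in brackets, and each black tick is the median of 10000 random lists matched on signal level. Blue points are lists called lower by camera with its preset correlation, red points lists called higher and grey points lists not called. No list was called with an estimated correlation, and cholesterol synthesis genes lie lowest at −0.50.

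Of 12 glutamatergic markers, 2 rose, 2 fell and 8 did not pass, and the vesicular transporter Slc17a6 fell by 0.84 (SE 0.13), while Slc17a7, another one, rose by 0.22 (SE 0.08) from a low level of 5.20. The forebrain factors Fezf2 (0.27, SE 0.07) and Emx2 (−0.24, SE 0.08) also changed. After cyclic loess none of the 12 rose and 4 fell, and Slc17a7 (0.10, limma adjusted p = 0.276) and Fezf2 (0.16, limma adjusted p = 0.105) did not pass. Of 11 GABAergic markers, 2 rose, 4 fell and 5 did not pass. The GABA-synthesizing enzymes Gad1 and Gad2 fell by 0.64 (SE 0.13) and 0.57 (SE 0.13) and the transporter Slc32a1 by 0.39 (SE 0.09), while the factor Dlx1 rose by 0.35 (SE 0.09). Neither list was called (camera adjusted p = 0.877 and 0.970).

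Markers of other cells did not move as 1 group. Of 13 neural progenitor markers, 3 fell (Nes, Gli3 by 0.25 with SE 0.06 and Vim by 0.16 with SE 0.05) and 10 did not pass, with a list median of −0.02 against −0.12 for level-matched lists (camera adjusted p = 0.828). Of 10 astrocyte markers, 2 rose and 4 fell, with the filament gene Gfap at −0.36 (SE 0.06), Aldoc at −0.23 (SE 0.06), Aldh1l1 at −0.21 (SE 0.06) and Glul (glutamine synthetase) at 0.21 (SE 0.06). The astrocyte list median was 0.08 against −0.18 for level-matched lists, of which 0.05% were as high, and after cyclic loess 5 rose and 2 fell (list median 0.09). DMSO replicate b minus DMSO replicate a also had a high median over these markers (0.08 against −0.05 for level-matched lists, 0.92% as high) and over the oligodendrocyte markers (0.16 against −0.01, 0.54% as high). Of 10 oligodendrocyte lineage markers, 5 fell, with Cnp at −0.47 (SE 0.07), Gpr17 at −0.47 (SE 0.09), the factor Olig1 at −0.35 (SE 0.07) and Pdgfra at −0.23 (SE 0.06). Neither of these 2 lists was called (camera adjusted p = 0.877 and 0.260). Of 14 fibroblast and endothelial markers, 7 fell, also when adjusted over the list alone, with Col1a1 (collagen) at −0.69 (SE 0.07), Tagln at −0.64 (SE 0.10), Acta2 (smooth muscle actin) at −0.62 (SE 0.06) and Col1a2 at −0.61 (SE 0.06). This list was called lower (camera adjusted p = 0.00401, median −0.16), but not with gene correlation estimated (adjusted p = 0.449 with an estimated correlation). Level-matched lists had a median of −0.10, and 19.96% of them were as low. The list median was −0.27 in drug batch 1 and −0.15 in drug batch 2, where the list was not called (camera adjusted p = 0.0544).

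The 2 lists called higher were both dim. Of 12 pluripotency markers, 6 rose, also when adjusted over the list alone, and 6 did not pass. Besides Dppa5a, the co-receptor Tdgf1 rose by 0.46 (SE 0.07), the transcription factor Nanog by 0.37 (SE 0.09) and Tcl1 by 0.34 (SE 0.09). Of 11 microglia and macrophage markers, 4 rose and 7 did not pass (1 rose when adjusted over the list alone), with the receptor Cx3cr1 at 0.44 (SE 0.10), C1qb at 0.24 (SE 0.09), Aif1 at 0.23 (SE 0.08) and Itgam at 0.21 (SE 0.08). Camera gave adjusted p of 0.00728 and 0.0289, and neither was called with gene correlation estimated (adjusted p = 0.524 with an estimated correlation). Their medians of 0.13 and 0.11 lay at those of level-matched lists (0.12 and 0.11). After cyclic loess the medians were −0.0103 and −0.0034, after quantile normalization −0.0139 and −0.019, and neither list was called after cyclic loess. The microglia list had a median of 0.16 in drug batch 1 and 0.05 in drug batch 2, where it was not called (camera adjusted p = 0.0714). DMSO replicate b minus DMSO replicate a had a median of 0.25 over the pluripotency markers, with 0.48% of level-matched lists as high.

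Camera called 6 further lists lower. Of 17 heat shock genes, 15 fell and 2 did not pass (16 fell when adjusted over the list alone), with the chaperones Hsph1 at −0.64 (SE 0.08), Chordc1 at −0.54 (SE 0.08), Fkbp4 at −0.50 (SE 0.07) and Dnajb1 at −0.45 (SE 0.08). Of 20 NRF2 targets, the antioxidant genes, 13 fell and 7 did not pass (15 fell when adjusted over the list alone), with Srxn1 at −0.68 (SE 0.08), Txnrd1 at −0.59 (SE 0.05), Gsr at −0.51 (SE 0.06) and Abcc4 at −0.42 (SE 0.07). Of 19 hypoxia and glycolysis genes, 2 rose, 13 fell and 4 did not pass (2 rose and 15 fell when adjusted over the list alone). The glycolytic enzymes Tpi1 (−0.72, SE 0.14), Pfkl (−0.65, SE 0.11) and Aldoa (−0.60, SE 0.11) and the glucose transporter Slc2a1 (−0.62, SE 0.06) led the falls. Of 25 respiratory chain genes, 18 fell and 7 did not pass (20 fell when adjusted over the list alone), with Sdhb at −0.45 (SE 0.06), Uqcrc1 at −0.39 (SE 0.07), Sdha at −0.38 (SE 0.06) and Ndufa8 at −0.31 (SE 0.06). Of 18 ER chaperones, 12 fell and 6 did not pass, also when adjusted over the list alone, with Xbp1, a regulator of the unfolded protein response, at −0.39 (SE 0.06), Hyou1 at −0.37 (SE 0.06), Hspa5 at −0.31 (SE 0.06) and Calr at −0.30 (SE 0.06). Of 29 cell cycle genes, 20 fell and 9 did not pass (21 fell when adjusted over the list alone), with the spindle kinase Bub1 at −0.48 (SE 0.09), Mki67 at −0.44 (SE 0.07), Kif20a at −0.40 (SE 0.07) and Rrm2 at −0.35 (SE 0.07).

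In the order just given, camera gave these 6 lists adjusted p of 5.33e-06, 0.000511, 0.00748, 0.000105, 0.00607 and 5.22e-05. None was called with gene correlation estimated (adjusted p = 0.356 with an estimated correlation for heat shock genes and NRF2 targets and 0.524 for the others). The estimated correlation within the NRF2 targets was 0.024, near the preset 0.01. The lost call of that list thus does not measure gene correlation alone. After cyclic loess 11, 8, 10, 5, 5 and 6 of their genes fell, while 2 hypoxia and glycolysis genes and 2 ER chaperones rose. Medians and those of level-matched lists were −0.34 and −0.17 for heat shock genes, −0.27 and −0.18 for NRF2 targets, and −0.34 and −0.17 for hypoxia and glycolysis genes. They were −0.23 and −0.21 for respiratory chain genes, −0.25 and −0.20 for ER chaperones, and −0.24 and −0.17 for cell cycle genes. Level-matched lists as low made up 0.20%, 4.07%, 0.02%, 29.1%, 18.0% and 5.55%, so the respiratory chain genes and ER chaperones stood little apart from genes of their level, and after cyclic loess neither was called (camera adjusted p = 0.143 and 0.408). In drug batches 1 and 2 alone the medians were −0.22 and −0.44 for hypoxia and glycolysis genes, −0.38 and −0.15 for ER chaperones, and −0.32 and −0.20 for cell cycle genes. The hypoxia and glycolysis list was not called in batch 1 (camera adjusted p = 0.0588) and the ER chaperones not in batch 2 (camera adjusted p = 0.197). SP600125 replicate a minus SP600125 replicate b had a median of −0.29 over the hypoxia and glycolysis genes, against −0.08 for level-matched lists, of which 0.02% were as low. It was 0.13 over both the ER chaperones and the cell cycle genes, with none of the level-matched lists as high.

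The remaining lists were not called and held genes moving both ways or few changes. Of 19 pro-apoptotic genes, 1 rose (Bmf, a BH3-only protein, 0.36, SE 0.09) and 4 fell, with Bnip3 at −0.64 (SE 0.17), Htra2 at −0.25 (SE 0.06) and Casp8 at −0.23 (SE 0.08). Of 11 aryl hydrocarbon receptor targets, 3 rose and 1 fell, with Cyp1a2 at 0.29 (SE 0.09), Tiparp at 0.21 (SE 0.07), the receptor's repressor Ahrr at 0.19 (SE 0.07) and Nqo1 at −0.36 (SE 0.09). After cyclic loess Cyp1a2 (0.18, limma adjusted p = 0.139) and Ahrr (0.08, limma adjusted p = 0.342) did not pass. Cyp1a1 and Cyp1b1, the classical targets of that receptor, had changes of 0.01 (SE 0.08, limma adjusted p = 0.934) and −0.03 (SE 0.06, limma adjusted p = 0.711), and both signs turned under quantile normalization and cyclic loess, after which Cyp1b1 passed at 0.16 (limma adjusted p = 0.0406). Of 22 ATF4 targets, 3 rose and 3 fell, with Vldlr at 0.33 (SE 0.06), Sesn2 at 0.33 (SE 0.08), Chac1 at 0.27 (SE 0.10) and Wars at −0.30 (SE 0.06). SP600125 replicate b carried part of the Chac1 rise, at 7.43 against 6.83 to 6.98 on the other SP600125 arrays. Of 21 p53 targets, 4 rose and 4 fell, with Eda2r at 0.32 (SE 0.07) and Rrm2b at −0.38 (SE 0.07). Of 17 FoxO targets, 4 rose and 4 fell, with Irs2 (insulin receptor substrate) at 0.35 (SE 0.07), Pdk4 at 0.34 (SE 0.08), Gadd45a at −0.34 (SE 0.06) and Sesn1 at −0.32 (SE 0.06). Of 17 NF-kB and inflammatory genes, 2 rose and 1 fell, with the chemokines Ccl5 at 0.29 (SE 0.07) and Cxcl2 at 0.23 (SE 0.08) and the inhibitor Nfkbia at −0.22 (SE 0.06). Of 13 interferon-stimulated genes, 2 rose and 2 fell, with Irf7 at 0.37 (SE 0.09), Ifit1 at 0.29 (SE 0.09), Ifit2 at −0.27 (SE 0.08) and Stat2 at −0.26 (SE 0.06). None of 15 ribosomal protein genes passed, and the largest change was that of Rpl7 (0.14, SE 0.06).

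Of 16 circadian clock genes, 2 rose and 4 fell, with the core activators Clock at −0.43 (SE 0.07) and Arntl at −0.30 (SE 0.06) and the repressors Bhlhe40 at 0.25 (SE 0.06) and Bhlhe41 at −0.25 (SE 0.08). Of 13 Notch pathway genes, 2 rose and 4 fell, with the effectors Hey2 at 0.32 (SE 0.10) and Hey1 at 0.31 (SE 0.05) and the regulators Nrarp at −0.31 (SE 0.08) and Dtx1 at −0.30 (SE 0.09). Of 11 Wnt targets, 5 fell, with Ccnd1, Lgr5 at −0.30 (SE 0.10), Znrf3 at −0.26 (SE 0.07) and Myc at −0.20 (SE 0.06). Of 11 TGF-beta and BMP targets, 1 rose and 2 fell, with Ccn2, a matricellular protein, at −0.61 (SE 0.07), Id2 at 0.34 (SE 0.09) and Skil at −0.24 (SE 0.06). Over the 21 lists not called, counts adjusted over the list alone were the same except for 4 lists. They were 1 up and 3 down for pro-apoptotic genes, 2 up and 1 down for ATF4 targets, 1 up and 1 down for NF-kB genes, and 2 up and 5 down for GABAergic markers. After cyclic loess the ATF4, FoxO and ribosomal lists were called higher (camera adjusted p = 0.000320, 0.00719 and 0.00299), and none of them with gene correlation estimated (adjusted p = 0.323, 0.395 and 0.442 with an estimated correlation). There 6 rose and 0 fell of the ATF4 targets, 7 rose and 2 fell of the FoxO targets, 5 rose and 2 fell of the p53 targets, 3 rose and 2 fell of the clock genes, and 2 ribosomal protein genes rose. Level-matched lists with medians as high made up 0% for ATF4 and FoxO targets, 3.50% for p53 targets, 0.79% for clock genes and 1.66% for ribosomal protein genes. DMSO replicate b minus DMSO replicate a had a median of 0.09 over FoxO targets, 0.04 over ribosomal protein genes and 0.15 over NF-kB genes, with 0.36%, 0.95% and 1.00% of level-matched lists as high. SP600125 replicate a minus SP600125 replicate b had a median of 0.08 over ribosomal protein genes, with 0.07% as high, and of −0.19 over ATF4 targets, with 4.04% as low. Median, mean and direction of the test did not share 1 sign for 7 of these lists, namely immediate early, ERK feedback, p53, clock, glutamatergic, GABAergic and astrocyte.

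After cyclic loess 32 of the named genes no longer passed in limma (adjusted p from 0.0506 to 0.810). Besides Mapk8, Slc17a7, Fezf2, Atf2, Cyp1a2 and Ahrr these were Aif1, Aldh1l1, Bhlhe41, C1qb, Cxcl2, Dtx1, Hey2, Htra2, Ifit1, Irf7, Itgam, Lgr5, Myc, Ndufa8, Nfkbia, Npy, Olig1, Pdgfra, Pdk4, Rrm2, Sesn1, Skil, Stat2, Tcl1, Vim and Wars. Rpl7 passed there (0.24, limma adjusted p = 0.0165). Bhlhe40, Chac1, Fosb, Glul, Id2 and Tiparp did not pass when each array was centred on its median, where Egr1 passed (−0.19, limma adjusted p = 0.0230), and Dlx1 did not pass after quantile normalization (limma adjusted p = 0.0524).

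Camera called 16 of the 37 lists with its preset correlation, 14 lower and 2 higher, and none with an estimated correlation. The estimated variant was not tried on simulated data, so its power with these arrays is not known. A list or gene family that it did not call is therefore not shown to be unchanged. Fry, which tests a list on its own and not against the other genes, called 21 lists. Among genes above the median level alone, 5 of the 16 kept their call (heat shock, cholesterol, presynaptic and postsynaptic genes lower, pluripotency markers higher), 10 lost it, 1 had no gene left, and 9 lists in all were called higher. Drug batch 1 alone, with 2 arrays against 2, gave 1 gene call, cyclic loess gave 5419, and a covariate for the olfactory receptor median, which follows the treatment closely, left 1 call (Nes).

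The second comparison asked whether the response differed between the drug batches. The change of Nes was −1.35 in batch 1 and −1.33 in batch 2, and that of Jun was −0.64 and −0.51. The 5 genes with the smallest interaction p were Wfdc6a (−0.27 in batch 1, 0.57 in batch 2), G370120E05Rik (0.29 and −0.52), Rdh18-ps (0.50 and 1.52), Lrrc10 (0.45 and −0.23) and Tcl1b2 (0.21 and 0.87). None passed in limma after adjustment (smallest adjusted p = 0.386), and 0 genes were called, while 1852 genes, or 9.29%, had an unadjusted interaction p under 0.05. Across genes, which are not independent replicates, the log2 changes of the batches correlated at r = 0.740. Batch 1 alone gave 1 call, with 4913 genes at an unadjusted p under 0.05, and batch 2 alone gave 7650. With 2 arrays per group in batch 1, a p that misses the threshold does not show that the batches acted alike.

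The third comparison set drug batch 2 against drug batch 1 with treatment as a term, as a check on the samples. In limma, 144 genes differed, of which 109 were higher and 35 lower in batch 2. The count moved with the arrays used. It was 26, 203, 42, 111 and 68 without SP600125 replicates a to e in turn. It was 79, 74, 76, 78 and 73 without DMSO replicates a to e in turn, and 31 without both DMSO replicate b and SP600125 replicate a. The labels do not say whether culture or hybridisation went with the drug lot.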

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

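All tests of Nes, the test of array spread, the olfactory receptor test, the cell share test and the position of each array along the response were chosen only after the result was seen.

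Single arrays stood apart from the other 4 of their group for 44 of 348 combinations of a group with a named gene or array summary, where chance gives about 1 in 20 (5%). The measure is the gap of the outermost array to its neighbour divided by the range of the group, with Dixon's critical value of 0.71 for 5 arrays. DMSO replicate b accounted for 19 of them and SP600125 replicate b for 16. DMSO replicate b lay below the other DMSO arrays for Thbs1 (0.936), Mblac2 (0.932), Slit2 (0.899), Gad2 (0.851), Elavl3 (0.847), Gad1 (0.840), Fos (0.817), Stmn2 (0.805), Map1b (0.784), Napb (0.764), Rgs4 (0.759), Ecel1 (0.757), Elavl4 (0.753), Sv2a (0.753), Fbln5 (0.724), Map1a (0.723), Mapt (0.722), Npy (0.717) and Slc17a6 (0.713). SP600125 replicate b lay above the other SP600125 arrays for Bnip3 (0.866), Cacna2d1 (0.824), Ecel1 (0.821), Gfap (0.809), Col1a1 (0.781), Gad1 (0.761), Nefl (0.749), Chac1 (0.739), Stmn2 (0.737), Mapt (0.736), Pfkl (0.734), Rgs4 (0.733) and Syp (0.719), and below them for Aqp8 (0.807), Hspa5 (0.765) and Sp140 (0.733). Gad1, Ecel1, Mapt and Stmn2 were listed for both b arrays and were higher on SP600125 replicate b than on DMSO replicate b. For Mapt these values were 8.65 and 8.53, and for Stmn2 10.76 and 10.59. SP600125 replicate a lay apart for Bhlhe40 (0.783), Jund (0.764) and Uqcrc1 (0.758), DMSO replicate a for Homer2 (0.734) and Map3k4 (0.714), and SP600125 replicate d for Nrarp (0.771) and Rrm2b (0.717). DMSO replicate d lay apart for Eda2r (0.879) and SP600125 replicate c for Wars (0.827).

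Along the response of drug batch 2, where 0 is the mean of its DMSO arrays and 1 the mean of its SP600125 arrays over 7650 genes, the batch 1 arrays lay at 0.126 (DMSO replicate a), 0.436 (DMSO replicate b), 1.11 (SP600125 replicate a) and 0.680 (SP600125 replicate b). Over 101 neuronal genes alone DMSO replicate b lay at 0.529 and SP600125 replicate b at 0.435, so there the order of the b arrays was reversed. For Nes each b array lay with its own group, at 7.71 for DMSO and 6.41 for SP600125. Without DMSO replicate b and SP600125 replicate a, 8469 genes changed and 16 lists were called. That fit kept SP600125 replicate b, and no fit left out both b arrays.

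Unnamed probe sets, which the comparisons of genes left out, also moved. Of 12146, 2448 were higher and 856 lower on the SP600125 arrays, with a median log2 change of 0.09. Over all probe sets 232 changed at least 2-fold, against 6 among the genes tested. How many of the 232 were unnamed was not counted.

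Bright genes were lower and dim genes higher on the SP600125 arrays, and all 5 of these arrays had a narrower spread of gene values than every DMSO array, which argues against a few arrays or 1 drug batch as the source. Olfactory receptor genes, not expected in these cells, rose in 54.4% of cases (559 of 1027, with 4 that fell), which is consistent with a weaker signal over background on all SP600125 arrays. Their median rise of 0.23 lay above that of genes of their level (0.11), and 258 still rose after cyclic loess (median 0.12, camera adjusted p = 6.33e-16, but adjusted p = 0.188 with an estimated correlation), so the trend with level was not the whole of it. The difference between DMSO replicates b and a also correlated with the batch 2 response across genes (r = 0.498, and 0.385 after the level trend was removed), so part of the response may lie along an axis of array or culture quality that exists without the drug. Signal over background itself was not measured, and whether treatment or handling gave the pattern stays open, since every SP600125 array shows it, as does a broad fall of abundant transcripts in treated cells, which was not tested.

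Neuronal and synaptic genes were lower on the SP600125 arrays, with a median of −0.39 over 101 genes. None of 10000 random lists matched on signal level and genomic length was as low (0%, matched median −0.23), which argues against signal level or gene length as the whole cause. Of 14 fibroblast and endothelial markers, 8 fell after cyclic loess (list median −0.26, camera adjusted p = 0.00311, but adjusted p = 0.323 with an estimated correlation, and not called in batch 2 alone before loess), while of 10 astrocyte markers 5 rose and 2 fell. After cyclic loess the mean of the first list minus that of the second went from −0.55 ± 0.03 to −0.89 ± 0.03 (mean ± SD over 5 arrays each, exact two-sided permutation p = 0.00794). The change was −0.34 in batch 1 and −0.33 in batch 2, so these markers moved apart, where a lower share of neurons alone would raise both. The 2 lists were picked after their opposite directions were seen, so this p-value is no separate support. A response of these markers themselves to SP600125 was not tested, so a lower share of neurons is not excluded. The neuronal genes were also lower in DMSO replicate b than in DMSO replicate a (median −0.25, with 0% of level-matched lists as low), so a difference between arrays that needs no drug may account for part of the fall, and a response of neuronal genes to SP600125 or a change in astrocytes stays open beside it.

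Nes fell most among the named genes, while the other 12 progenitor markers had a median change of −0.00 (−0.0049, lowest −0.25). A loss of progenitor cells would be expected to lower those as well, so the markers as a set argue against a broad loss. Gli3 and Vim did fall, as did 20 of 29 cell cycle genes (6 after cyclic loess), so a loss of some progenitors is not excluded. After cyclic loess Nes still fell by 1.18 (limma adjusted p = 1.64e-07), which argues against the trend with level as the cause. Only 1 probe set measured Nes, so a fault of that probe set cannot be told apart from a change of the transcript. A response of Nes itself to SP600125 remains a hypothesis that may be followed up.

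Chance division of the arrays was examined with 100 splits, the real one included (for drug batch, 100 of the 210 ways to divide 10 arrays into 4 and 6). For 3 results only the real division reached its count. The other splits were not held balanced for drug batch, or for treatment in the batch test, though the fit kept that term. The real division is balanced, so these splits are no equal comparison and cannot exclude chance. The real split gave 9351 changed genes against 3744 in the highest other split, which exchanged the b arrays, and 1 split reached that count. It gave 6 genes at 2-fold against 2 (1 split) and 144 genes between batches against 1 (1 split). For gene lists chance is not clearly excluded, since 4 of the 100 splits reached the real count of 16 and the highest other also gave 16. The other 3 were among 22 splits that exchanged 1 DMSO array with 1 SP600125 array, which gave 11 to 16 lists. A split that exchanged 2 arrays each way still gave 14 lists, with 0 changed genes. The count of lists thus tells the real division little from other ones.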

How the results depend on the processing

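Cyclic loess, centring on named genes, leaving out DMSO b with SP600125 a, the olfactory receptor covariate, and an estimated correlation after cyclic loess were chosen after seeing the data. Of the 9351 changed genes, all kept their sign with array weights and in each leave-one-out fit. These fits share most of their data with the primary analysis, so they are a weak check. After cyclic loess 9189 kept their sign, and in batch 1 alone 9298. The replicate block gave 8252 changed genes (2954 up), 6 at 2-fold and 16 lists. Deviations of arrays sharing a letter correlated at 0.029, −0.208, 0.079, −0.037 and 0.101 for a to e, and only c correlated best with its own letter. These values gave no sign of pairs, but they cannot show that samples sharing a letter were made apart. The count of genes responding differently between batches was 0 in limma in every fit that tested it, with 1852 at an unadjusted p under 0.05 in the primary analysis.

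Quantile normalization gave 5991 changed genes (1497 up) and 4 higher lists. Median centring of each array, which moved the median of all genes from −0.03 to −0.13, gave 1500 rises, 12 genes at 2-fold and 297 between batches. Genes above the median level alone gave 534 rises, 9 higher and 4 lower lists, and 320 genes between batches; fewer genes were tested. There 10 of the 16 called lists lost their call. Trend and robust settings gave 310 genes between batches, and array weights 16 at 2-fold. Batch 1 alone gave 1 changed gene (0 up, 1 down, 1 at 2-fold), with fewer arrays, and batch 2 alone 2206 rises, 35 at 2-fold and 1 higher list. Cyclic loess gave 5419 changed genes (1882 up, 3537 down) and 4 higher lists, and 4358 of the 9351 genes were called in the same direction. Without DMSO b and SP600125 a, 11 genes passed 2-fold and 31 differed between batches. All probe sets gave 6116 rises and 232 at 2-fold, and camera with an estimated correlation 0 lists, also after cyclic loess (0).

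The olfactory receptor covariate left 1 changed gene (0 up, 1 down, 1 at 2-fold), Nes at −1.19, with 1564 genes at an unadjusted p under 0.05, and 7 lists (0 higher, 7 lower). Batch and this covariate explained 86.3% of the treatment term, the median SE grew 2.68 times, the median change of the 9351 genes was 52.5% of its size and 81.2% kept their sign. Values that turned sign were the pan-neuronal (0.0141), microglia (−0.0143) and pluripotency (−0.071) medians, Ahrr −0.0024, Atf2 0.0805, Atf3 −0.0774, Bhlhe41 0.065, Bnip3 0.106, C1qb −0.0756, Casp8 0.0504, Cx3cr1 −0.0605, Cyp1a1 −0.3209, Ecel1 0.0738, Fbln5 0.0327, Fezf2 −0.0791, Gad1 0.0531, Ifit1 −0.0207, Irf7 −0.1095, Itgam −0.0143, Nanog −0.0204, Nefl 0.221, Sema3c 0.1511, Slc17a7 −0.0944, Tcl1 −0.0179 and Wfdc6a −0.1213.

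Leaving out single arrays gave 7673 to 9687 changed genes (2392 to 3475 up, 5106 to 6355 down), 4 to 24 at 2-fold (19 without DMSO replicate b, 24 without SP600125 replicate b), 26 to 203 between batches, and 15 to 17 lists (1 to 2 higher, 14 to 15 lower). Of 161 named genes past the threshold, 17 lost it in at least 1 such fit, and so did the microglia list. Other sign changes concerned 6 genes and 2 dim lists. Cyp1a1 was −0.1236 with quantile normalization, −0.0921 with median centring, −0.0069 in batch 1, −0.1126 with cyclic loess, and −0.0404 to 0.0622 over the leave-one-out fits. Cyp1b1 was 0.104 with quantile normalization, 0.1626 with cyclic loess and 0.0073 with centring on named genes. Lrrc10 was −0.1139 with quantile normalization, −0.0615 with median centring, −0.0315 with array weights, −0.2322 in batch 2, −0.1122 with cyclic loess, −0.0414 without DMSO b and SP600125 a, and −0.046 to 0.1057 over the leave-one-out fits. In batch 1, G370120E05Rik was 0.2854, Rpl7 −0.005 and Wfdc6a −0.2658. The microglia and pluripotency medians were −0.019 and −0.0139 with quantile normalization and −0.0034 and −0.0103 with cyclic loess. The cause of these shifts was not tested except where given. Signal over background was not measured. The trend of the changes with signal level limits what small changes of dim genes show.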

Other observations

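Gene families grouped by symbol after the data were seen added further groups. Of 177 families tested after cyclic loess, cadherins (Cdh) and the beta cluster of protocadherins (Pcdhb), adhesion molecules, were among those lower. Of 22 Pcdhb genes, 14 fell and 1 rose in the primary analysis, with a median of −0.29 against −0.06 for genes of their level, and 12 of 23 Cdh genes fell, with a median of −0.29 against −0.04. Kinesins (Kif) fell in 22 of 38 cases, with a median of −0.23 against −0.08, and centrosomal genes (Cep) in 18 of 37, with a median of −0.17 against −0.01. Camera after cyclic loess called these 4 families lower (adjusted p = 0.000878, 0.0108, 0.00198 and 0.000260), and none with gene correlation estimated (adjusted p = 0.396, 0.396, 0.411 and 0.329 with an estimated correlation). It also called Alg, Ppp, Zcchc and Zfp genes lower (adjusted p = 0.0439, 0.0206, 0.0191 and 0.0177), and none with gene correlation estimated (adjusted p = 0.290, 0.412, 0.290 and 0.412 with an estimated correlation). Of 347 Zfp genes, 130 fell and 26 rose, with a median of −0.13 against −0.04 for genes of their level. Under quantile normalization, both median centrings and cyclic loess the medians of these 8 families lay between −0.39 and −0.09. The 12 genes with the stem Pcdh were not called, with a median of −0.11 after cyclic loess (adjusted p = 0.150).

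Keratin-associated protein genes (Krtap) rose in 34 of 44 cases, with a median of 0.37 against 0.07 for genes of their level, late cornified envelope genes (Lce) in 12 of 19, with a median of 0.28 against 0.08, and vomeronasal receptor genes (Vmn) in 60 of 167, with a median of 0.15 against 0.085. After cyclic loess camera called all 3 higher (adjusted p = 2.70e-13, 0.000599 and 0.000118), and none with gene correlation estimated (adjusted p = 0.188, 0.294 and 0.188 with an estimated correlation). The families Ces, Defb, Muc, Prss, Sprr, Taar, Tas and Wfdc were also called higher after cyclic loess (adjusted p from 0.000878 to 0.0439), and none with gene correlation estimated (adjusted p = 0.188 to 0.391 with an estimated correlation). Under the same 4 scalings the medians of these 11 families lay between 0.05 and 0.40. All 11 were dim, with mean log2 levels from 3.46 (Vmn) to 5.11 (Krtap). The olfactory receptor genes were dim as well (3.92) and also rose. A rise of the transcripts of these families cannot be told apart from a weaker signal over background on the SP600125 arrays. Keratins (Krt) were not called after cyclic loess (adjusted p = 0.404). Of 52, 13 rose, with a median of 0.11 against 0.12 for genes of their level, and the sign turned under quantile normalization (−0.0075). Large-subunit ribosomal protein genes (Rpl) had a median of 0.03, against −0.13 for genes of their level, and the sign turned to −0.07 when each array was centred on its median. After cyclic loess 9 of 36 rose and 1 fell, and camera called this family, the small-subunit genes (Rps) and the Klf genes higher (adjusted p = 0.000260, 0.00142 and 0.0300), but none with gene correlation estimated (adjusted p = 0.527, 0.501 and 0.412 with an estimated correlation). The Rps and Klf medians also turned sign under that centring, from 0.03 to −0.07 and from 0.0002 to −0.10.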
